A study of Homo sapiens with 9 samples.

How the data were processed

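RNA was sequenced from HEK293A cells, a flat-growing subclone of the human embryonic kidney line HEK293, in which the p65 gene had been knocked out. Per the labels' protocols, the cells were transfected with an empty vector, with p65 WT or with a form named p65 2CS, and 24 h later received TNF at 20 ng/mL for 2 h. The labels hold 3 libraries of each of the 3 groups, numbered 1 to 3 for vector, 4 to 6 for p65 WT and 7 to 9 for p65 2CS, so that no number is shared between groups and no pairing was used. The labels do not say what 2CS stands for, nor whether the libraries of a group came from separate cultures. If they did not, the p-values measure only the spread between these samples, which may be technical. All 9 libraries come from TNF-treated cells, so the response to TNF itself was not compared.

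Messenger RNA was captured by its poly-A tail, fragmented and copied from random primers, per the labels' protocols, which allow for a strand-specific or a non-specific library without saying which was made. Reads were aligned with HISAT2 2.0.5, per the submitters' processing notes. The counting tool, its strand setting and the genome build are not given in the sources used here. The deposited values are raw read counts per gene, whole numbers without normalization, for 58735 genes with a symbol, position, strand, length and biotype. All 58735 gene identifiers, their start, end and strand and their symbols were those of GENCODE release 29, whose coordinates are on GRCh38, and positions are given on that build by this match. Without a known strand setting, reads of overlapping genes and of antisense partners cannot be told apart, and genes with near-identical copies may have had their reads split or dropped.

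The total count per library was 17923114 to 20162267 with vector, 15989601 to 16507689 with p65 WT and 17146134 to 25068515 with p65 2CS. A count of 0 over a whole group allows up to 3 counts, or 0.0524 CPM with vector, 0.0627 with p65 WT and 0.0489 with p65 2CS. Folds against such a group were computed against that floor and are written as "at least". With 1 to 3 counts over a group, the ratio is given with its exact 95% binomial counting interval (Clopper-Pearson). Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Within each group, every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 1.91 to 2.6. They were treated as separate samples as labelled, which this spread cannot show, since library preparation also adds to it.

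The deposited counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by edgeR's expression filter over the 3 groups (18195 tested, 40540 not), libraries were scaled by TMM, and the quasi-likelihood F test was run in a single fit of all 9 libraries with a mean per group. Adjusted p is the Benjamini-Hochberg value over all genes tested, with a threshold of 0.05. CPM is the count scaled in the usual way by the TMM-scaled library total, computed here from the deposited counts, and is given as mean ± SD over the 3 libraries of a group. Log2 folds are given with the standard error implied by the F test. The contrasts were p65 WT against vector, p65 2CS against vector, p65 2CS against p65 WT, and the mean of both p65 forms against vector. The last of these defined p65-responsive genes (adjusted p under 0.05 and a log2 fold of at least 1 in size, RELA left out). With equal groups and an equal spread in both p65 groups it is independent of the contrast between the 2 forms. Where the spread differs, this holds only approximately. The median change between the forms over those genes was tested with fry and with an exact permutation of per-library mean log2 CPM (prior count 2), two-sided, whose smallest possible p with 3 against 3 libraries is 0.1.

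Before the data were examined, 23 gene lists were fixed: 6 lists of NF-kB targets (feedback inhibitors, subunits other than p65, chemokines, cytokines and growth factors, adhesion and receptor genes, survival genes), whose union is called the NF-kB target list, and lists for interferon response, antigen presentation, immediate early genes, TNF receptor and IKK signalling, palmitoyl transferases and thioesterases, unfolded protein and integrated stress response, heat shock, p53 targets, cholesterol synthesis, glycolysis and hypoxia, S phase and mitosis, markers of nephron epithelium and neural genes, leukocytes, and fibroblasts and endothelium, mitochondrially encoded genes, cytosolic ribosomal proteins and replication-dependent histones. Each list was counted over all genes tested and adjusted over the list alone, and was compared with the other genes by camera with a preset correlation of 0.01, adjusted over lists and comparisons. List p-values printed in the report are the stricter adjusted values with an estimated correlation.

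Genes were named by a rule fixed at the same time. RELA came first. Then, for each pairwise comparison, the rule took up to 6 largest rises and 6 largest falls among protein-coding genes past the threshold with at least 2 CPM in the higher group and CPM ranges that did not overlap, and up to 4 called members of each list with the smallest p, or at most 2 of a list with no called member. The values of the NF-kB genes named for p65 WT against vector were also taken for p65 2CS against p65 WT. Genes outside the rule are marked as chosen after their values were seen.

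The fit was tested on simulated data before use, with the gene means of the vector libraries and the sizes of all 9 libraries, over 17255 genes. Changed genes were drawn from those with at least 1 CPM with vector, so recovery was not measured for genes near silence there. Of genes changed 1.5-fold, 85.5% were recovered in p65 WT against vector, 64.1% in p65 2CS against vector and 79.7% in p65 2CS against p65 WT. Of genes changed 2-fold, 89.8%, 92.2% and 91.7% were recovered in the same order, and of genes changed 4-fold 98.3%, 100% and 98.2%. Genes simulated without a change made up 9.05%, 7.07% and 7.41% of the calls, above the share of 0.05 that the threshold sets. The simulation changed far fewer genes than the data did, with rises and falls equally likely, and gave 199, 184 and 378 calls. Recovery and false calls may therefore differ in the data. Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE size factors, library totals without a composition correction, no expression filter, a filter of CPM at least 1 in 3 libraries, fits of only the 2 groups compared, a test against a log2 fold of 0.5, a minimum log2 fold of 1, RELA left out of the counts, and each library left out in turn. For the lists they were an estimated correlation and fry, and for the responsive genes 2 other ways of choosing them and no minimum fold.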

Results

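The series asked how p65, the RELA-encoded subunit of the transcription factor NF-kB, and its palmitoylation bear on gene expression after TNF. Cells labelled as p65 knockout were given an empty vector, p65 WT or p65 2CS, and RNA was sequenced from 3 libraries of each group. Library totals lay between 15989601 and 25068515 counts (17923114 to 20162267 with vector, 15989601 to 16507689 with p65 WT and 17146134 to 25068515 with p65 2CS), and 18195 of 58735 genes had enough reads to be tested. The libraries fell apart by group: over the 500 most variable genes the first principal component held 88.2% of the variance and the second 7.42%. Values below are CPM as mean ± SD with n = 3 per group, or log2 folds ± standard error.

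RELA itself (ENSG00000173039, chromosome 11, 65653596 to 65663094 on the minus strand of GRCh38) was present at 67.7 ± 1.61 CPM with vector, 9003 ± 943 CPM with p65 WT and 25518 ± 1382 CPM with p65 2CS. It was the third most abundant tested gene with p65 WT and the most abundant with p65 2CS, where it took 2.56% of all counts, against 0.884% with p65 WT and 0.00685% with vector. The log2 fold was 7.05 ± 0.05 for p65 WT against vector and 8.56 ± 0.05 for p65 2CS against vector. Between the 2 forms RELA differed by 1.5 ± 0.04 on the log2 scale, or 2.83-fold, with more RELA transcript in p65 2CS cells (edgeR adjusted p = 1.4e-30). The counts cannot separate plasmid transcripts from those of the knocked-out locus, and protein was not measured.

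**Figure D1:**
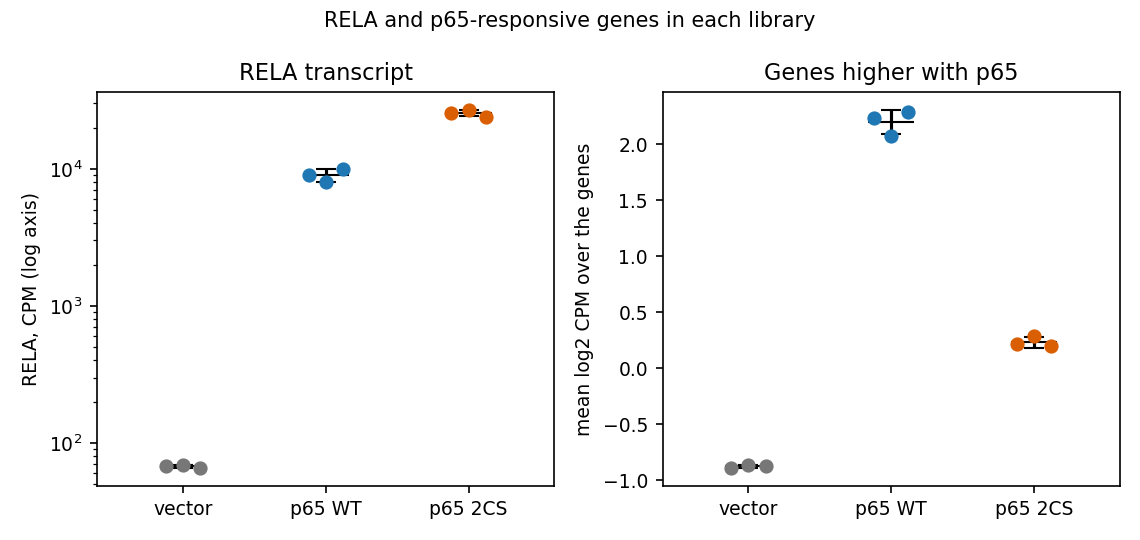
Left, RELA transcript in CPM on a log axis, right, the mean log2 CPM over the 791 genes higher with p65, for each of the 9 libraries by group, with points for libraries and bars for the mean ± SD. RELA was highest with p65 2CS (25518 CPM on average), while the gene set was highest with p65 WT (2.2, against 0.23 with p65 2CS and -0.88 with vector).

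With p65 WT in place of vector, the NF-kB target genes rose together, from near silence for many of them. CCL20, a chemokine that attracts CCR6-bearing cells, had no read with vector and 151 ± 0.7 CPM with p65 WT, at least 2890-fold higher. Adhesion molecules of activated endothelium rose as well: SELE (E-selectin) from 0.0653 ± 0.113 to 405 ± 14.3 CPM, ICAM1 from 0.246 ± 0.0440 to 404 ± 24.6 CPM, and VCAM1 from no read to 21.8 ± 1.19 CPM, at least 416-fold. All vector reads of SELE came from replicate 2, without which its log2 fold of 12.37 became 15.85, a fitted value that depends on the prior count. CD40, a costimulatory receptor, rose from 0.532 to 192 CPM. Of the 79 measured genes of the NF-kB target list, 63 rose and 2 fell, or 64 and 2 adjusted over the list alone, with a median log2 fold of 1.31 (limma camera adjusted p = 9.2e-05). Genes changed in p65 WT against vector numbered 5244, of which 2976 were higher and 2268 lower, or 2561 and 3642 with libraries scaled by their totals alone. Among those changed at least 2-fold, 1141 were higher and 56 lower.

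Each of the 6 NF-kB lists moved upward with p65 WT. Of 13 chemokine genes 11 rose and 0 fell, with a median log2 fold of 5.50, or 5.2 with genes that lack reads set at their floor. CXCL8 went from 0.0879 to 20.5 ± 2.11 CPM and CXCL1 from 0.0712 ± 0.123 to 16 ± 1.2 CPM, both neutrophil attractants of a family with similar sequences. All vector reads of CXCL1 came from replicate 1, without which its log2 fold of 7.71 became 11.21. The log2 fold of CXCL8 was 7.77, and 7.23 to 8.47 with each library left out in turn. Among 14 cytokine and growth factor genes 11 rose and 0 fell, including IL32 (3.81 to 96.6 CPM), EBI3, a shared cytokine chain (0.160 to 27.1 CPM), and CSF1, the macrophage growth factor (18.2 to 65.8 CPM). TNF itself had 1 count over the vector libraries and 13.4 ± 1.04 CPM with p65 WT, a ratio of 765 with a counting interval of 137 to 30300. Of 22 adhesion and receptor genes 18 rose and 2 fell. These counts were identical when adjusted over each list alone.

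The negative feedback arm of the pathway rose as well. Of 13 feedback inhibitors 11 rose and 0 fell, over all genes and over the list alone. TNFAIP3, a deubiquitinase that restrains the pathway, rose from 6.98 ± 0.828 to 217 ± 4.43 CPM, and NFKBIA, the inhibitor that retains NF-kB in the cytoplasm, from 36.4 ± 0.467 to 317 ± 6.26 CPM. TNIP1, a partner of TNFAIP3, and CYLD, another deubiquitinase, rose by 1.2 ± 0.04 and 1.28 ± 0.05 on the log2 scale. All 4 of the other subunit genes rose, by 2.89 ± 0.04 for NFKB2, 2.74 ± 0.06 for RELB, 1.15 ± 0.04 for NFKB1 and 0.52 ± 0.08 for REL. Of 13 survival genes 8 rose and 0 fell (9 and 0 over the list alone), among them TRAF1 (2.44 to 35.4 CPM), BIRC3, an inhibitor of apoptosis (2.28 to 15.1 CPM), GADD45B (157 to 311 CPM) and IER3 (53.2 to 98.9 CPM).

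**Figure D2:**
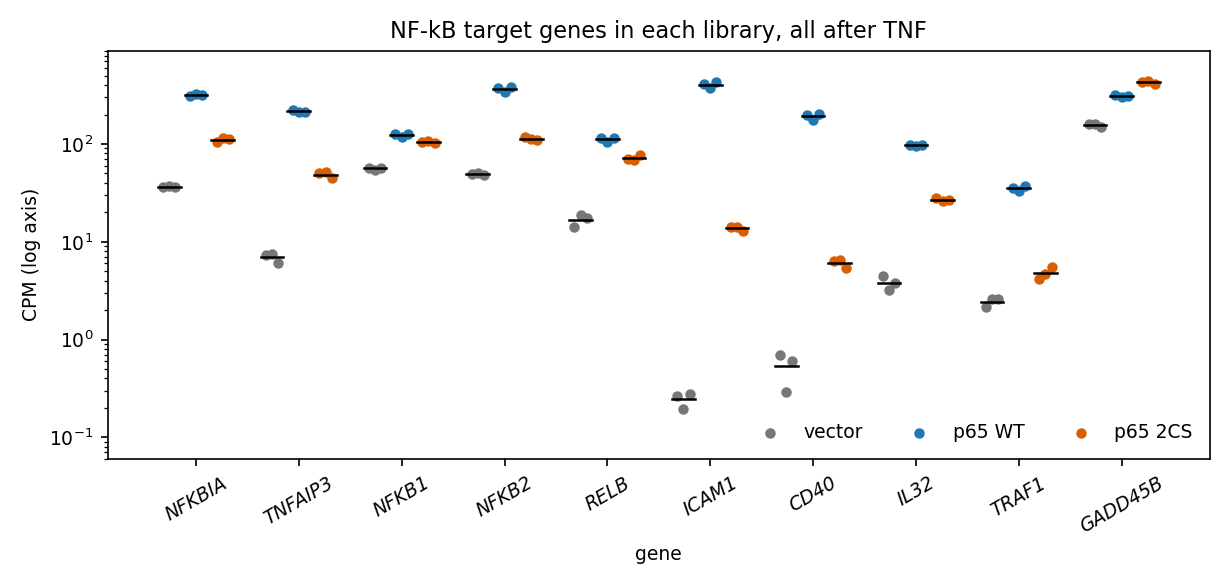
CPM on a log axis of 10 NF-kB target genes in each of the 9 libraries, all from TNF-treated cells, with points for libraries, black bars for group means and colours for groups. ICAM1 averaged 0.246 CPM with vector, 404 with p65 WT and 13.7 with p65 2CS, while GADD45B averaged 157, 311 and 428 CPM.

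Beyond those lists, antigen presentation genes rose with p65 WT, 13 of 16 measured with 0 falls (limma camera adjusted p = 0.0032). TAPBP and TAP1, of the machinery that supplies MHC class I with peptides, rose from 53.1 to 175 CPM and from 26.8 to 85.6 CPM. HLA-F rose from 5.62 to 22.7 CPM. Of 29 interferon response genes 11 rose and 1 fell (limma camera adjusted p = 0.033), including the transcription factor IRF1 (14.6 to 58.6 CPM), OAS3 (27.8 to 57.2 CPM) and the RNA sensor IFIH1 (4.75 to 15 CPM). Both lists had equal counts over the list alone. Of 7 fibroblast and endothelial markers 3 rose and 0 fell, with an adjusted p = 0.071 with an estimated correlation. They included the endothelial genes VWF (7.22 to 25.1 CPM) and CDH5 (0.0979 to 10.5 CPM), whose reads with vector all came from replicate 2.

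Immediate early genes split with p65 WT: of 32 measured, 8 rose and 12 fell (11 and 14 over the list alone), with a median log2 fold of -0.06 and a mean of 0.14. EGR3 and ZFP36, an RNA-destabilising protein, rose from 27.3 to 83.2 CPM and from 7.01 to 35.9 CPM, while ATF3 fell from 329 to 194 CPM and JUN from 1307 to 935 CPM. In the unfolded protein and integrated stress list 7 of 23 rose and 9 fell, with PPP1R15A higher (158 to 317 CPM) and TRIB3 (32.1 to 14.4 CPM) and the cystine transporter SLC7A11 (27.4 to 13.2 CPM) lower. TNF receptor and IKK signalling genes gave 6 rises, 4 falls and 11 uncalled genes, led by the kinases IKBKE (3.99 to 28.5 CPM) and MAP3K8 (14.3 to 37.3 CPM). Palmitoyl transferases and thioesterases, the enzymes that add and remove palmitate, gave 3 rises and 5 falls among 30 (3 and 2 over the list alone), with the thioesterase LYPLA2 rising from 55.8 to 94.2 CPM. The 8 calls of this list became 4 or 5 without vector replicate 1, 2 or 3 or p65 WT replicate 5 or 6, and the 10 calls of the TNF receptor list became 6 without p65 WT replicate 6.

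Other lists held small or mixed changes with p65 WT, and camera called none of those that follow. Rises and falls were 6 and 2 of 22 p53 targets, where the death receptor FAS rose from 31.0 to 55.8 CPM, 3 and 1 of 14 heat shock genes (3 and 2 over the list alone), 7 and 3 of 30 S phase and mitosis genes, and 3 and 2 of 24 cholesterol synthesis genes. They were 5 and 7 of 23 glycolysis and hypoxia genes (6 and 8 over the list alone), 4 and 4 of 12 nephron and neural markers, 4 and 0 of 13 mitochondrially encoded genes, and 1 and 0 of 4 leukocyte markers. Ribosomal protein genes gave 14 rises and 7 falls among 83 (13 and 6 over the list alone), a balance that turned to 4 rises and 14 falls when libraries were scaled by their totals alone. The same scaling gave 2 rises and 8 falls for cholesterol synthesis, 5 and 6 for S phase and mitosis, 2 and 4 for heat shock, 4 and 5 for nephron and neural markers and 1 and 1 for mitochondrially encoded genes. Without vector replicate 2 the ribosomal calls were 9, without p65 WT replicate 6 they were 11, and without p65 WT replicate 4 the mitochondrially encoded genes gave 0 rises and 2 falls.

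Falls of at least 2-fold with p65 WT numbered 56, among the 2268 genes lower. Of 36 measured replication-dependent histone genes 18 fell and 1 rose (20 and 1 over the list alone), with a median log2 fold of -0.63 (limma camera adjusted p = 0.037). HIST1H4H fell from 19.5 ± 1.83 to 8.06 ± 0.875 CPM, HIST1H2AC from 25.1 to 14.2 CPM and HIST1H1C from 31.7 to 19.4 CPM. Most transcripts of this class lack a poly-A tail and their genes resemble each other closely, so that their reads are uncertain in poly-A selected libraries. U2AF1L5 (34.6 ± 25.3 to 10.6 ± 2.08 CPM), a near-identical copy of U2AF1, is likewise uncertain, and its log2 fold of -1.7 became -0.97 without vector replicate 3.

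With p65 2CS in place of vector, many of the same pathway genes rose, to lower levels than those seen with p65 WT. CCL20 reached 17.2 ± 1.74 CPM, at least 329-fold above vector, SELE 24.3 ± 2.03 CPM, ICAM1 13.7 ± 0.840 CPM and VCAM1 2.92 ± 0.424 CPM, at least 55.7-fold. TNFAIP6, a secreted hyaluronan-binding protein, had no read with vector and 2.63 ± 0.184 CPM with p65 2CS, at least 50.2-fold. Of the 79 genes of the NF-kB target list 49 rose and 2 fell (52 and 4 over the list alone), with a median log2 fold of 0.71, or 0.69 with genes that lack reads at their floor (limma camera adjusted p = 0.00019). Genes changed in p65 2CS against vector numbered 4263, of which 2193 were higher and 2070 lower, or 1955 and 2382 with libraries scaled by their totals alone. Among those changed at least 2-fold, 388 were higher and 41 lower.

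The NF-kB lists with p65 2CS gave rises in 10 of 13 chemokines, 10 of 13 feedback inhibitors, all 4 other subunits and 7 of 14 cytokine and growth factor genes (9 over the list alone), each with 0 falls. Of 22 adhesion and receptor genes 10 rose and 1 fell (11 and 2 over the list alone), and of 13 survival genes 8 rose and 1 fell (8 and 2). RELB rose by 2.11 ± 0.07 on the log2 scale, NFKB2 by 1.2 ± 0.04, NFKB1 by 0.90 ± 0.04 and REL by 0.60 ± 0.08. TNFAIP3 reached 48.6 ± 3.42 CPM and NFKBIA 111 ± 6.01 CPM. TNFRSF9, a costimulatory receptor, rose from 2.42 to 14.8 CPM, and GADD45B from 157 to 428 CPM. Interferon response genes gave 10 rises and 1 fall among 29 (limma camera adjusted p = 0.014), with IRF1 at 30.8 ± 0.315 CPM and the RNA sensor DDX58 rising from 6.32 to 13.8 CPM. Antigen presentation genes gave 4 rises and 1 fall among 16, led by TAPBP (53.1 to 79.7 CPM) and TAP1 (26.8 to 46.5 CPM), and camera did not call the list.

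Of 83 ribosomal protein genes 62 fell and 0 rose (70 and 0 over the list alone), with a median log2 fold of -0.12 and adjusted p = 0.084 with an estimated correlation. RPL39 fell from 362 to 298 CPM and RPS24 from 784 to 678 CPM. Of 24 cholesterol synthesis genes 13 fell and 0 rose (14 and 0), with a median of -0.17 (limma camera adjusted p = 0.018), among them HMGCS1 (215 to 177 CPM) and INSIG1 (77.8 to 58.8 CPM). In the unfolded protein and stress list 9 of 23 fell and 1 rose (13 and 1), with a limma camera adjusted p = 0.039. TRIB3 (32.1 to 19.6 CPM) was lower and PPP1R15A (158 to 242 CPM) higher. Histone genes gave 18 falls and 0 rises among 36 (19 and 1), with a median of -0.51 (limma camera adjusted p = 0.013), including HIST1H2AC (25.1 to 12.1 CPM) and HIST1H1C (31.7 to 18.7 CPM).

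The remaining lists with p65 2CS against vector were mixed. Immediate early genes gave 2 rises and 11 falls among 32 (4 and 12), with adjusted p = 0.053 with an estimated correlation. JUNB rose from 50.0 to 108 CPM and JUN fell from 1307 to 921 CPM. TNF receptor and IKK signalling genes gave 5 rises and 1 fall among 21, with adjusted p = 0.17 with an estimated correlation, including MAP3K8 (14.3 to 27.1 CPM) and IKBKE (3.99 to 7.98 CPM). Glycolysis and hypoxia genes gave 2 rises and 9 falls among 23 (2 and 12), where PGK1, a glycolytic kinase, rose from 539 ± 7.09 to 1736 ± 64.5 CPM and NDRG1 fell from 331 to 262 CPM. Rises and falls were 1 and 8 of 30 S phase and mitosis genes (2 and 9), 5 and 4 of 14 heat shock genes (6 and 4), 2 and 5 of 22 p53 targets, 0 and 3 of 30 palmitoyl transferases and thioesterases, and 1 and 5 of 13 mitochondrially encoded genes. They were 1 and 4 of 12 nephron and neural markers, 1 and 0 of 4 leukocyte markers and 2 and 2 of 7 fibroblast and endothelial markers. The 7 calls among p53 targets became 4 without vector replicate 2 or p65 2CS replicate 9. The 6 calls among mitochondrially encoded genes became 3 in 1 alternative, and stayed at 5 or 6 with each library left out in turn.

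Set directly against p65 WT, p65 2CS gave lower levels of most NF-kB target genes although its RELA transcript was higher. Of the 79 genes of the list 53 were lower and 2 higher (54 and 3 over the list alone), with a median log2 fold of -0.76 (limma camera adjusted p = 9.2e-05). CD40 was 31.7-fold lower with p65 2CS (192 against 6.03 CPM), ICAM1 29.4-fold lower (404 against 13.7 CPM), EBI3 24.2-fold lower (27.1 against 1.06 CPM) and SELE 16.5-fold lower (405 against 24.3 CPM). CCL20 was 8.7-fold lower, with a log2 fold of -3.12 ± 0.06 (adjusted p = 1.1e-33). Genes changed in p65 2CS against p65 WT numbered 5685, of which 2431 were higher and 3254 lower, a balance that turned to 3098 higher and 2820 lower with libraries scaled by their totals alone. Among those changed at least 2-fold, 92 were higher and 884 lower.

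The difference between the 2 forms was uneven across the NF-kB targets. Falls with p65 2CS were 9 of 13 chemokines, 9 of 14 cytokine and growth factor genes, 16 of 22 adhesion and receptor genes, 10 of 13 feedback inhibitors and 3 of 4 other subunits, each with 0 rises apart from 1 feedback inhibitor when adjusted over the list alone. TNFAIP3 was 4.45-fold lower, NFKB2 3.22-fold lower, NFKBIA 2.86-fold lower, RELB 1.54-fold lower and NFKB1 1.19-fold lower, while REL did not pass the threshold (log2 fold 0.08 ± 0.07, adjusted p = 0.47). CXCL3, CXCL1 and CXCL8 were 8.3-fold, 4.76-fold and 3.59-fold lower, IL32 3.59-fold, TNF 5.79-fold and CSF1 1.75-fold. Of 13 survival genes 6 were lower and 2 higher (7 and 2 over the list alone), with adjusted p = 0.10 with an estimated correlation. TRAF1 was 7.4-fold lower and BIRC3 2.34-fold lower, while GADD45B was 1.38-fold higher with p65 2CS. The preset correlation called the survival list (adjusted p = 0.0383), a call lost without p65 WT replicate 4 or 5 or p65 2CS replicate 7, with adjusted p of up to 0.0544.

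**Figure D3:**
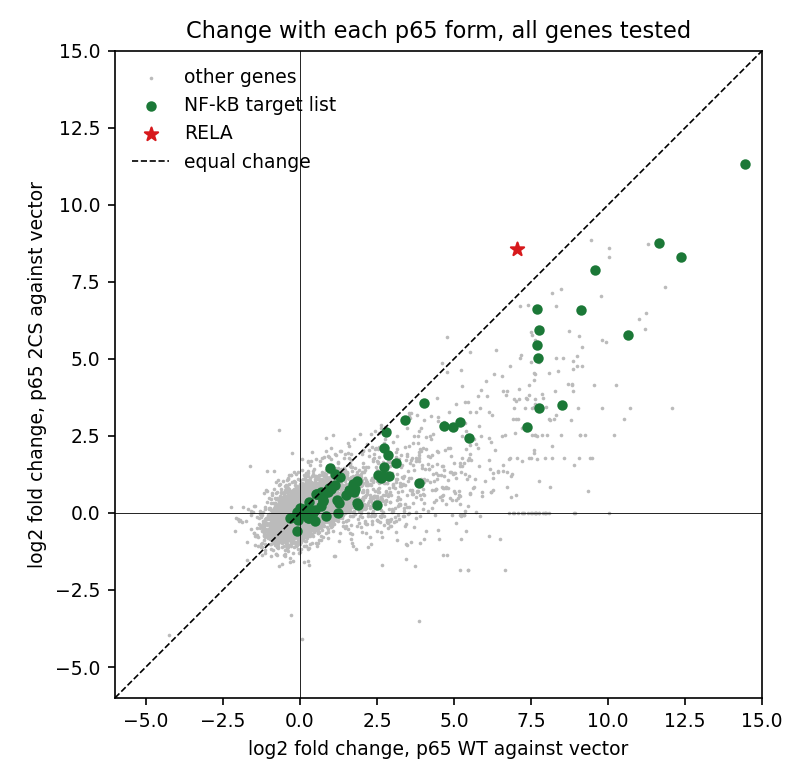
Log2 fold of each of the 18195 tested genes for p65 WT against vector on the x axis and p65 2CS against vector on the y axis, with the NF-kB target list in green, RELA as a red star and a dashed line at equal change. Most target genes lie below the dashed line (median log2 fold 1.31 on the x axis and 0.71 on the y axis), and RELA lies above it (7.05 and 8.56). Folds of genes without reads in a group depend on the prior count.

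The p65-responsive genes as a whole gave the same contrast. Averaged over both forms, 791 genes other than RELA were at least 2-fold higher than with vector. Their median log2 fold was 3.12 with p65 WT and 1.22 with p65 2CS. Between the forms it was -1.87 (quartiles -3.29 and -0.89), or a median per-gene ratio of p65 2CS to p65 WT of 0.273. Of the 791 genes, 625 were lower with p65 2CS, 9 higher and 157 not called. The per-library mean of these genes was 2.2 ± 0.109 log2 CPM with p65 WT and 0.23 ± 0.049 with p65 2CS (limma fry p = 1.07e-07, and exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Only 28 genes were at least 2-fold lower with p65. Their fall rested partly on vector replicate 3, where their mean log2 CPM was 1.151, against 0.566 and 0.737 in replicates 1 and 2. In the p65 libraries it lay between -0.427 and 0.011. The median of the 28 genes between the forms was 0.18, with 2 higher, 2 lower and 24 not called. Its sign depended on which genes and libraries were used. As a set these 28 genes did not pass the test between the forms (limma fry p = 0.779, and exact permutation p = 1 on library means), though fry passed without p65 WT replicate 4 or 6.

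Of the other gene groups, camera with an estimated correlation called antigen presentation between the forms and none of the 4 that follow it. Of 16 antigen presentation genes 12 were lower with p65 2CS and 0 higher (13 and 1 over the list alone, limma camera adjusted p = 0.0028), including HLA-F (2.92-fold), TAPBP (2.19-fold), TAP1 (1.83-fold) and HLA-C (1.36-fold). Of 83 ribosomal protein genes 68 were lower and 0 higher (70 and 2), with a median of -0.13 and adjusted p = 0.23 with an estimated correlation. RPS3, for example, stood at 1887 ± 36.3 CPM with p65 WT and 1662 ± 20.2 CPM with p65 2CS. Cholesterol synthesis genes gave 13 falls and 1 rise among 24 (15 and 1), with adjusted p = 0.15 with an estimated correlation, including INSIG1 (80.5 against 58.8 CPM). Of 7 fibroblast and endothelial markers 4 were lower and 0 higher, with adjusted p = 0.055 with an estimated correlation. VWF and CDH5 were 2.68-fold and 4.39-fold lower. Interferon response genes gave 7 falls and 2 rises among 29 (limma camera adjusted p = 0.464), and IRF1 was 1.9-fold lower.

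The other lists were not called between the forms by camera. Falls and rises with p65 2CS were 12 and 4 of 32 immediate early genes (14 and 4 over the list alone), where EGR3 and ZFP36 were 2.75-fold and 2.56-fold lower and MYC 1.32-fold higher, and 6 and 1 of 22 p53 targets, where FAS was 1.93-fold lower. They were 9 and 5 of 23 unfolded protein and stress genes (10 and 5), 13 and 2 of 30 S phase and mitosis genes, with PCNA 1.2-fold lower and CDT1 1.22-fold higher, and 9 and 2 of 23 glycolysis and hypoxia genes (10 and 2), where PGK1 was 2.07-fold higher. They were 10 and 0 of 13 mitochondrially encoded genes (11 and 0), 5 and 0 of 30 palmitoyl transferases and thioesterases, where LYPLA2 was 1.65-fold lower, 6 and 4 of 21 TNF receptor and IKK signalling genes (6 and 6), 4 and 5 of 14 heat shock genes, 6 and 0 of 12 nephron and neural markers, led by PAX8 (4.28 against 0.657 CPM), and 5 and 6 of 36 histone genes (4 and 6). Of 4 leukocyte markers 0 passed the threshold, the nearest being ITGAM (2.24 ± 0.377 CPM with p65 WT and 1.45 ± 0.341 CPM with p65 2CS, adjusted p = 0.097) and CSF1R (0.523 ± 0.0969 and 0.955 ± 0.329 CPM, adjusted p = 0.138). Mitochondrially encoded genes gave 3 calls without p65 WT replicate 4 or p65 2CS replicate 7, palmitoyl genes 3 without p65 WT replicate 5, and histone genes 6 or 7 without p65 WT replicate 4 or 5 or p65 2CS replicate 7 or 8. With library totals alone the TNF receptor list turned to 5 falls and 8 rises.

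The largest falls by fold with p65 2CS were genes detected almost only with p65 WT. SFTPA2, a lung surfactant protein, stood at 35.8 ± 1.27 CPM with p65 WT and 0.189 ± 0.0640 CPM with p65 2CS, and shares most of its sequence with SFTPA1. The keratin KRT74 stood at 11.3 ± 0.627 and 0.0703 ± 0.122 CPM, with all p65 2CS reads in replicate 9, without which its log2 fold of -7.29 became -10.7. The protease gene CTSE had 7.88 ± 1.25 CPM with p65 WT and 2 counts over the p65 2CS libraries, both in replicate 8, a ratio of 242 with a counting interval of 66.5 to 2000. LCN1, a tear lipocalin, had 3.20 ± 0.253 CPM and no read with p65 2CS, at least 65.4-fold. The largest rises by fold with p65 2CS under the rule for named genes, RELA apart, were of genes under 4 CPM and of EIF3CL: FOXD4L1, of a multicopy family, rose from 0.335 to 3.53 CPM, SOX30 from 0.669 to 2.19 CPM, DMGDH from 0.838 to 2.41 CPM and NPR3 from 0.859 to 2.24 CPM. The rise of EIF3CL (log2 fold 1.43 ± 0.31), a near-identical copy of EIF3C, rested on p65 2CS replicate 9 and was 0.30 without it (adjusted p = 0.20).

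The 2 comparisons with vector shared many calls. In both, 1072 genes other than RELA were higher and 807 lower, against 358 and 258 expected from independent lists of those sizes. Since both use the same vector libraries, unchanged groups were simulated against them. Over 20 simulations these gave 0.2 calls on average in each comparison and an overlap of 0, which with so few calls does not measure the overlap that shared controls add to real changes. The log2 folds correlated across 15430 genes at 0.555, where the simulation gave 0.490 from the shared controls alone, and genes are not independent replicates. The covariance was 0.0610 against 0.0102 in the simulation, a difference of 0.0508. The 3 vector libraries were not split between the comparisons, since 1 side would hold a single library, so part of the excess may come from them. Of the 1140 genes other than RELA at least 2-fold higher with p65 WT, 961 were lower with p65 2CS than with p65 WT, 1 was higher and 178 were not called. Of the same 1140 genes, 462 were higher with p65 2CS than with vector. Choosing genes on a high p65 WT level favours such falls. The choice of the 791 genes weights both forms alike, which avoids this as far as their spread is equal.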

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

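The tests of a single share of responding cells, of the amount of RELA transcript, of S phase genes and of both PGK1 explanations were chosen only after the result was seen. Against vector, 147 genes were higher with p65 WT and lower with p65 2CS, and 97 were lower with p65 WT and higher with p65 2CS. These genes drew attention because the 2 forms moved them in opposite directions. Calls in the same direction were far more common, with 1072 genes higher and 807 lower in both comparisons. The number of opposite calls that independent lists would give was not computed, so the counts show no excess of them. All 147 and all 97 passed the test of p65 2CS against p65 WT, which nearly follows from choosing genes called in opposite directions. Many of the changes were small, with log2 folds of 0.08 and -0.08 for EEF1A1 and 0.07 and -0.07 for UHRF1. KLHDC7B (1.83 and -1.17) was among the largest. The counts of 147 and 97 were not repeated under other scalings, which shift the balance of calls against vector. MARCKS stood at 249 CPM with vector, 329 with p65 WT and 217 with p65 2CS, KCNA1 at 5.63, 8.71 and 3 CPM, GDF15 at 3.94, 5.96 and 2.46 CPM, and KLHDC7B at 0.954, 3.38 and 0.388 CPM. In the other direction, BRD2 stood at 871, 826 and 1130 CPM, MIDN at 254, 210 and 291 CPM and PIK3IP1 at 17.4, 13.2 and 21 CPM. Apart from GDF15, these genes were chosen after their values were seen. The edgeR call of KLHDC7B with p65 2CS was lost without vector replicate 3 (log2 fold -0.77, adjusted p = 0.288) and without p65 2CS replicate 7 (-1.01) or 9 (-0.82), and in a fit of the 2 groups compared alone (-1.17, adjusted p = 0.0538), and its log2 fold was -2.06 without p65 2CS replicate 8. GDF15 lost its call with p65 WT without vector replicate 2 (0.46) or p65 WT replicate 6 (0.5), and with p65 2CS without vector replicate 1 (-0.6) or 3 (-0.58) or p65 2CS replicate 9 (-0.52), and BRD2 with p65 WT without vector replicate 1 (-0.07).

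The p65-responsive genes were lower with p65 2CS than with p65 WT (median log2 fold -1.87 over 791 genes). A scaling shift from the larger share of counts that RELA takes was argued against as the whole cause by its size. The TMM factors lay between 0.9808 and 1.015, and RELA took 2.56% of counts with p65 2CS. The median was therefore bound to change little. It was -1.88 with library totals alone or with RELA left out, whichever lay nearer 0. A smaller share of responding cells, alike for every gene, would leave each gene the same part of its rise. Over 311 genes with at least 5 CPM with p65 WT, the part kept had a median of 11.5% and an interquartile range of 23.4 percentage points, against 2.65 to 3.75 in 100 simulations of a single share. Taking genes by their level with p65 WT favours a low part kept, so 11.5% does not describe all 791 genes. A different amount of RELA stays open, because the lowest p65 2CS library held 2.42 times the RELA CPM of the highest p65 WT library, so that form and amount cannot be told apart, and the change from p65 WT to p65 2CS, which the design names, may act with it or alone.

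Replication-dependent histone genes were lower with both forms (median log2 fold -0.63 with p65 WT and -0.51 with p65 2CS). A lower carry-through of RNA without a poly-A tail would lower other such RNA alike, but over 44 genes of small nuclear, nucleolar and similar RNA the lower of both medians was -0.15. Of these genes 1 was called higher with p65 WT and 0 with p65 2CS. This covers those genes only, and does not test a loss limited to histone RNA. Fewer cells in S phase would lower S phase genes. The list of S phase and mitosis genes had a lower median of -0.05. Its rises and falls were 7 and 3 with p65 WT, and 1 and 8 with p65 2CS. Since the list mixes both kinds of genes, it cannot decide for S phase alone. Read sharing among near-identical histone genes was not tested and may bear on single members.

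PGK1 followed RELA over the 3 groups, at 539, 841 and 1736 CPM. A general rise of glycolysis genes was argued against by the median of the other 22 genes of the list, -0.11 with p65 2CS against vector. Reads from a plasmid element shared with PGK1 are a candidate source. The PGK1 rise was 3.35 ± 0.32% of the RELA rise with p65 WT and 4.7 ± 0.004% with p65 2CS, a ratio of 1.4. Equal parts would follow from a shared element only with an unchanged PGK1 gene and the same proportion of element to RELA in both plasmids. Neither is known, and gene totals hold no position along the transcript. This source and a change of the PGK1 gene itself therefore cannot be told apart.

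Other splits of the libraries were counted for each comparison. For each pairwise comparison, 1 of the 10 splits of its 6 libraries, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Fitted on those libraries alone, the real split gave 4991 genes for p65 WT against vector, 4378 for p65 2CS against vector and 5462 for p65 2CS against p65 WT, and the highest other split gave 0 in each. For vector against all p65 libraries, 2 of 84 splits, the real one included, gave as many genes as the real one (1378), a share under 0.05. The highest other split (3395) set the 3 p65 WT libraries against the rest, and that of the 3 p65 2CS libraries gave 1231. The count thus shows that libraries cluster by group. It does not exclude chance differences between cultures, since the labels do not say whether libraries of a group are separate cultures.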

How the results depend on the processing

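The alternatives were all chosen before the data were examined. No paired analysis was possible because the groups share no replicate numbers. The count of changed genes moved most with a minimum fold. Tested against a log2 fold of 0.5 it was 1204 for p65 WT against vector, 282 for p65 2CS against vector, 907 for p65 2CS against p65 WT and 735 for the mean of both forms, and with a log2 fold of at least 1 it was 1197, 429 and 976 for the pairwise comparisons, since fewer genes reach such folds. Leaving out each library gave 4493 to 5480, 3231 to 4410, 4771 to 5760 and 3774 to 4738 genes. With library totals alone, p65 WT against vector gave 2561 higher and 3642 lower genes (41.3% higher, against 56.8%), the mean of both forms 2234 and 3091 (42%, against 54.9%), p65 2CS against p65 WT 3098 and 2820 (52.3%, against 42.8%) and p65 2CS against vector 1955 and 2382 (45.1%, against 51.4%). The median over the 791 genes stayed negative in its 20 alternatives, from -2.06 to -0.29, and past the threshold in those with a test, since none was run with DESeq2 (-1.97). It was -0.29 with no minimum fold, which takes in 2612 genes, and -0.95 with genes taken from p65 2CS against vector. The median over genes lower with p65 (0.18) was not stable: -0.14 with CPM at least 1 in 3 libraries, 0 with no minimum fold, 0.77 with genes taken from p65 WT against vector and -0.71 with genes taken from p65 2CS against vector. The last pair, with both of which limma fry called the set, follows from choosing genes on 1 of the groups compared. The cause of the others was not tested. Leaving out each library gave -0.23 (p65 2CS replicate 7) to 0.33 (p65 WT replicate 4), with -0.09 without vector replicate 3 and 0.24 without p65 WT replicate 6, and fry called the set without p65 WT replicate 4 or 6. RELA stayed at 6.98 to 7.13, 8.52 to 8.6 and 1.43 to 1.58, and the overlap of calls at 1487 to 2181. Of 660 alternatives to 33 list tests called with the preset correlation 645 kept the call and 15 lost it. None of those with a direction changed it. The estimated correlation, used for most printed list p-values, lost the ribosomal protein, immediate early and TNF receptor calls for p65 2CS against vector. For p65 2CS against p65 WT it lost the ribosomal protein, cholesterol synthesis, survival, and fibroblast and endothelial calls. It also lost the fibroblast and endothelial call for p65 WT against vector. Of 3212 alternatives to 189 gene values 3197 kept direction and call, 12 lost the call (KLHDC7B, GDF15, BRD2 and EIF3CL) and 3 gained it (TRAF3, p65 2CS against p65 WT, log2 fold 0.14 in each). Depth limits genes at a few counts, where a group at 0 allows 0.0489 to 0.0627 CPM.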

Other observations

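The test of the NF-kB target list against other responsive genes was chosen only after the result was seen, as were BATF, AC092666.1 and LINC01198. Many genes that were all but silent with vector were transcribed with p65 WT. At most 3 counts over the vector libraries and at least 2 CPM with p65 WT were seen for 93 genes past the threshold, of which 54 were protein coding. Their median was 4.13 CPM with p65 WT and 0.17 CPM with p65 2CS, 52 were called higher with p65 2CS than with vector, and 91 lower with p65 2CS than with p65 WT. Choosing genes on a high p65 WT level favours such falls. ZAN stood at 43.6 ± 6.7 CPM with p65 WT and 13.2 ± 2.3 CPM with p65 2CS, VSTM1 at 24.7 ± 3.7 and 1.06 ± 0.23 CPM, APOL6 at 16 ± 1.1 and 0.392 ± 0.34 CPM, and BATF, a transcription factor of lymphocytes, at 5.98 ± 1.7 and 0.0635 ± 0.014 CPM. Long noncoding RNAs were among them, with AC092666.1 at 28.9 ± 2.7 and 0.0653 ± 0.059 CPM and LINC01198 at 15.7 ± 1.7 and 0.0388 ± 0.067 CPM, the latter from replicate 7 alone. The genes at least 8-fold higher with p65 WT, RELA left out, held 291 protein-coding genes, 55 lincRNA, 34 antisense and 26 processed pseudogene entries. The last 2 kinds are uncertain without a known strand or with similar copies.

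A hypothesis from these data is that the NF-kB target list may fall less by fold from p65 WT to p65 2CS than other responsive genes do. The log2 fold between the forms was compared, not the part of the rise kept, and genes were not matched for their level with vector. Among the 791 genes, 43 list members had a median log2 fold of -1.52 between the forms and 748 others -1.89. Within 4 bins of the mean response the mean difference was 0.682, with a two-sided permutation p = 0.00425 over genes, which are not independent replicates. The test was chosen on, and run in, the same genes and libraries that prompted the hypothesis, so it adds no independent evidence for it.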
